A study of Mus musculus with 4 samples.

How the data were processed

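CUT&RUN, in which an antibody-tethered nuclease cuts and releases the DNA around a bound protein, was carried out with an anti-HA antibody on all-lymphoid progenitors sorted from mouse bone marrow. Per the labels, the cells came from C57BL/6 mice with a Tcf7-YFP reporter allele, were transduced with a retrovirus carrying a Thy1.1 marker, and were cultured for 2 days on irradiated OP9 stromal cells with stem cell factor, Flt3 ligand and IL-7 before Thy1.1-positive, Mac1-negative cells were sorted. The 4 libraries form 2 groups of 2: cells given HA-tagged NFIL3, and cells given untagged NFIL3, in which the antibody has no HA tag to bind and which therefore measure its background. The labels put all 4 libraries in batch 7.

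Per the submitters' processing notes, Trimmomatic 0.39, Bowtie2 2.5.1, SAMtools and HOMER 4.11 were used with the mouse genome build mm39. The data analysed are 1 HOMER peak table of the whole series. Per the file headers, the authors deposited for each peak its position, a peak score, the annotation of its position against Ensembl transcripts, the signed distance to the nearest transcription start site (TSS), the nearest gene, the fraction of G and C bases, the density of CpG dinucleotides, and the matches of HOMER's NFIL3 motif. The deposited peak score is a whole number with no stated scale. How the libraries were combined, how the untagged control entered peak calling and which filters were applied are not given in the sources used here. The table names no library, so it holds 0 columns of per-library values, and the depth per library and the replicate error are unknown. The planned comparison of the tagged with the untagged libraries per peak could therefore not be made, and no p-value here measures the spread between libraries. The tests run across peaks or genes of 1 list, which are not biological replicates. Wilson 95% intervals cover counting error within the list only. Beside a count of 0, the limit given in words is 3 counts of the total, and the plotted interval is Wilson's.

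Peak positions are printed 1-based on mm39 as the table gives them. The score was used only within the list. Because scores are whole numbers, the planned subsets of highest scores, 50% and 10% of the peaks, were taken at the nearest boundaries, scores of 5 or more and 8 or more. Each peak belongs to the gene of the nearest annotated TSS, which is a long non-coding RNA gene for 5646 of the peaks. A gene without an assigned peak can therefore still lie near a peak that belongs to a neighbour. For the gene lists, a peak within 50 kb of the TSS of a protein-coding gene was required. Symbols were matched to the 21900 protein-coding genes of the RefSeq table of assembly GRCm38.p6, used for names only. Of the 7045 protein-coding symbols in the peak table, 6877 matched directly or through a unique synonym. The number of list members with a peak was compared with that of all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 11 lists. Of the 285 list entries, 1 gene had no match. Score differences were tested on the median with a two-sided permutation test of 100000 resamples, whose smallest possible p is 1e-05.

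The motif matches are 15 bases long and their offsets run from 0 to 155 within the 170-bp peaks, counted from the first base of the peak. Matches on both strands of a near-palindromic site were merged into 1 site by their 8-base core. No mm39 sequence was used, so the planned control windows beside the peaks, the 13 other planned motifs and a random placement of peaks were not run. In their place, the motif share was compared between peaks of different score, with a two-sided Fisher's exact test and Mantel-Haenszel odds ratios within strata of GC content, CpG density and annotation class. This comparison, the tests on 8-base cores, the counts of list genes at a score of 8 or more, within 1 kb, with a motif match and without Nfil3, and the tests between pairs of lists were chosen after the table was seen. The promoter score tests within classes of GC content were not planned either. A score test on the D-box core was planned. It was run on any NFIL3 motif match, and the core alone became an alternative after the table was seen.

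The gene lists, the other tests and the rule for named genes were fixed before the data were examined. The rule names a panel of 16 regulators and receptors whether or not they have a peak, the nearest genes of the 10 highest-scoring peaks, the 3 genes of each list with the highest-scoring peak within 50 kb, and the 5 protein-coding genes with the most peaks. Of the genes that this rule names, 1 is not reported here. Alternatives included other distance limits and score boundaries, promoter peaks alone, peaks with a motif match alone, and removal of Nfil3.

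Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. The tests were tested on simulated data. With scores drawn for 17572 peaks, a planted difference of 1 score unit was called in 100% of 100 runs of the test on medians, and with no difference planted it called 0% of 100 runs, since medians of tied whole numbers seldom differ, while the same test on means called 6%. With random peak-bearing genes among 21900, a list planted with a peak in most of its members was called in 100% of 100 runs. Of 1000 lists with nothing planted, 1.4% were called. The planted share was larger than that of any gene list here, so power at the shares seen was not tested. The simulated genes all had the same chance of a peak. The 1.4% therefore does not show how often lists are called where genes differ in that chance.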

Results

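The data comprised 17572 peaks of 170 bp from anti-HA CUT&RUN in mouse lymphoid progenitors, 2 libraries from cells transduced with HA-tagged NFIL3 and 2 from cells with untagged NFIL3 as the antibody background. NFIL3 is a basic leucine zipper transcription factor required for the development of innate lymphoid cells (ILCs). The study asks where it binds during ILC specification. The peak list carries 1 score per peak and no value per library, so the level of each peak in the untagged control and the replicate error are not reported, and the depth is unknown. Of the peaks, 16959 lay on chromosomes 1 to 19, 598 on X, 9 on Y and 6 on unplaced sequences. The score had a median of 4 and ranged from 2 to 58. Scores of 4 or less made up 57.3% of the list, and 1672 peaks (9.52%) scored 8 or more. The peaks were assigned to 10452 nearest genes.

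Among the listed peaks, the highest scores fell on Nfil3 itself, followed by an intergenic site and a set of promoters and introns. The peak numbers, which follow the score, have gaps even among the first 10 of each chromosome (142 of 200 present). Peaks with high scores may therefore be missing from the list. The peaks with scores of 58 (chromosome 13, 53122661 to 53122830) and 48 (chromosome 13, 53121723 to 53121892) both lay in exon 2 of the 2-exon gene Nfil3 (ENSMUSG00000056749), and neither held an NFIL3 motif match. Another Nfil3 peak, with a score of 15, lay in intron 1, 624 bp downstream of the TSS (53134401 to 53134570), also without a match. The next peak, with a score of 40, was intergenic, 4.32 kb upstream of Mettl16, in AT-rich sequence with 27.6% GC and no motif match. Promoter peaks followed at Adnp, which encodes a chromatin-associated homeobox protein (score 29, 62 bp upstream of the TSS), at Wbp2 (score 27, 345 bp upstream), at the mitochondrial coenzyme Q gene Coq10b (score 24, 125 bp upstream) and at the interferon-gamma receptor gene Ifngr1 (score 22, 395 bp upstream). The remaining peaks of the highest 10 were in an intron of Vmp1, an autophagy gene (score 23), in an intron near Fggy (score 23), and in an intron nearest to a long non-coding RNA gene without a symbol on chromosome 16 (score 24). Among these 10 peaks, those at Adnp, Wbp2, Coq10b and Vmp1 held an NFIL3 motif match. The cores were TGACGTAA at Adnp (chromosome 2, 168049057 to 168049064), TTACGTAA at Wbp2 (chromosome 11, 115978198 to 115978205), TTACATAA at Coq10b (chromosome 1, 55091767 to 55091774) and TTACATAA at Vmp1 (chromosome 11, 86504945 to 86504952).

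Most peaks were distal, and promoter peaks had higher scores. Intergenic peaks made up 43.4% of the list (7627 peaks, 95% interval 42.7 to 44.1), intron peaks 39.8% (6995), promoter peaks 10.9% (1916, 95% interval 10.5 to 11.4), peaks at transcription termination sites 3.01% (529) and exon peaks 2.85% (500). The median score was 6 at promoters (mean 6.63 ± 2.76 SD, n = 1916) and 4 at intron and intergenic peaks together (mean 4.50 ± 2.00 SD, n = 14622). The difference in median of 2 score units gave p = 1e-05 in a two-sided permutation test, the smallest value the test can give. The difference was 1 score unit among peaks with up to 40% GC (190 promoter peaks, p = 1e-05), 2 among those with 40 to 50% GC (481 promoter peaks, p = 1e-05) and 1 above 50% GC (1245 promoter peaks, p = 3.00e-05), by the same permutation test. These tests within classes of GC content were not planned. Among peaks with a score of 8 or more, the promoter share was 33.3% (556 of 1672, 95% interval 31.0 to 35.5). The intergenic share there was 24.0%.

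**Figure D1:**
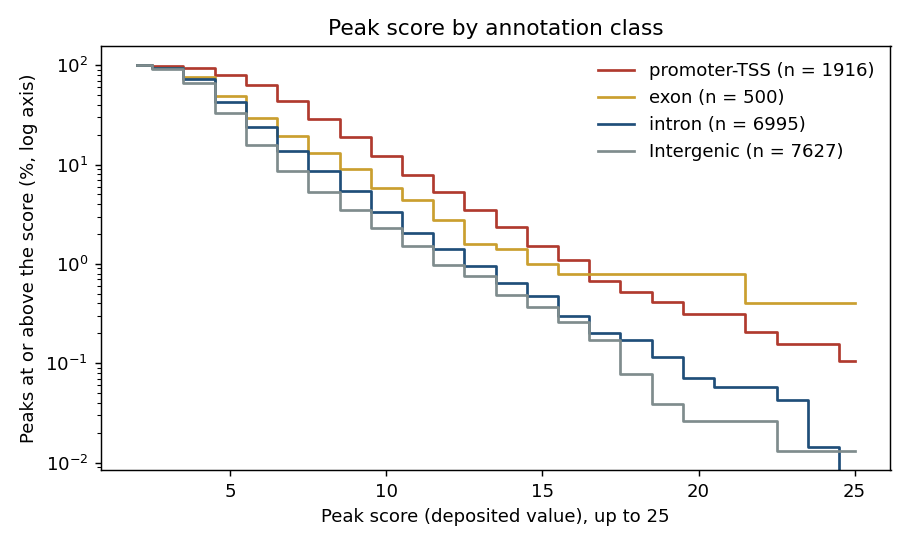
Percentage of peaks (log axis) at or above each score from 2 to 25, for promoter, exon, intron and intergenic peaks, as step lines. The promoter line lies above the intron and intergenic lines from a score of 3 to 24, with median scores of 6 at promoters and 4 at intron and intergenic peaks.

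The NFIL3 motif was found in 12.1% of the peaks (2128 of 17572, 95% interval 11.6 to 12.6), and its share was larger at higher scores. It was 7.26% among peaks with a score of 2 (89 of 1226, 95% interval 5.94 to 8.85), 10.5% at a score of 5 (334 of 3172), 20.6% at a score of 8 (122 of 593), 28.1% at a score of 10 (70 of 249) and 47.1% at scores of 16 and over (32 of 68, 95% interval 35.7 to 58.8). At scores of 8 or more and under 8 the shares were 27.1% (453 of 1672) and 10.5% (1675 of 15900), an odds ratio of 3.16 (95% interval 2.80 to 3.56, two-sided Fisher's exact p = 5.81e-70). The odds ratio was 4.32 (95% interval 3.80 to 4.91) within 10 classes of GC content of about equal size. The shares at promoters (12.6%), introns (12.8%) and intergenic sites (11.2%) lay close together over all scores. At scores of 8 or more the share was 21.0% at promoters (117 of 556), 29.9% in introns (178 of 596) and 29.1% between genes (117 of 402). Peaks with a match had a median score of 5 (mean 5.83 ± 3.06 SD, n = 2128) and peaks without one a median of 4 (mean 4.61 ± 2.10 SD, n = 15444), a difference of 1 score unit (p = 1e-05, two-sided permutation test, the smallest value the test can give).

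**Figure D2:**
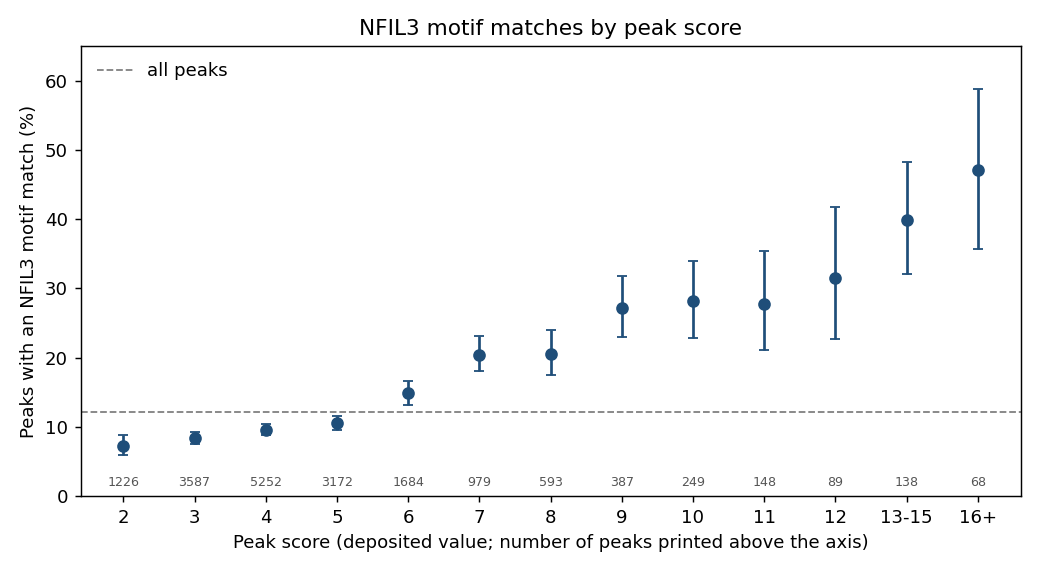
Percentage of peaks with at least 1 NFIL3 motif match (vertical axis) by peak score (horizontal axis), as points with 95% Wilson intervals, with the number of peaks printed above the axis. The share is 7.26% at a score of 2 and 47.1% at 16 and over, against 12.1% over all peaks (dashed line).

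The matches resolved into 2293 sites with 46 different 8-base cores, counting a core and its reverse complement as the same. The most frequent was TTATGTAA (TTACATAA on the other strand), with 484 sites or 21.1%, followed by TTATGCAA with 160 sites and TGATGTAA with 155. The full palindrome TTACGTAA, the D-box bound by NFIL3 and by the PAR-bZIP activators DBP, TEF and HLF, had only 34 sites. These lay in peaks with a mean score of 8.88 ± 5.03 (SD, n = 34), and 17 of the 34 in peaks with a score of 8 or more (95% interval, in percent, 34.1 to 65.9). For TTATGTAA the corresponding share was 30.6% (148 of 484, 95% interval 26.6 to 34.8), and for TTATACAA it was 6.15% (4 of 65, 95% interval 2.42 to 14.8). TGACGTAA, which contains a CpG, lay in promoters at 41.9% of its sites (18 of 43, 95% interval 28.4 to 56.7), against 10.5% for TTATGTAA (51 of 484, 95% interval 8.11 to 13.6). A D-box core (TTACGTAA or TTATGTAA) was present in 9.81% of peaks scoring 8 or more and in 2.19% of the others (two-sided Fisher's exact p = 3.02e-47).

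Among the 11 gene lists, the joint list of circadian clock and PAR-bZIP genes had a larger share of members with at least 1 peak than other genes. This held within 50 kb, at a score of 8 or more, within 1 kb of a TSS and with a motif match, counts that draw on the same peaks. Counting within 50 kb was planned, and the other counts were chosen after the data were seen. Of its 26 members, 15 (57.7%, 95% interval 38.9 to 74.5) had a peak within 50 kb, against 28.6% of the other 21874 protein-coding genes (odds ratio 3.40, two-sided Fisher's exact adjusted p = 0.00723). For peaks with a score of 8 or more the count was 9 of 26 against 4.83% of other genes (odds ratio 10.4, exact adjusted p = 2.39e-05). Within 1 kb of a TSS it was 9 of 26 against 8.59% (odds ratio 5.63, exact adjusted p = 0.0023), and for peaks with a motif match it was 9 of 26 against 4.91% (odds ratio 10.3, adjusted p = 2.74e-05). Per1, a repressor component of the clock, carried 3 peaks, with scores of 16 (172 bp downstream of an annotated TSS), 12 (145 bp upstream) and 9 (657 bp upstream). The last of these held TTACGTAA at chromosome 11, 68985318 to 68985325. Nr1d1, which encodes the nuclear receptor REV-ERB alpha, carried a peak with a score of 16 in intron 1 with TTATGTAA at chromosome 11, 98664906 to 98664913, and a promoter peak with a score of 7. Por, Per2, Tef and Per3 also had peaks, with highest scores of 13, 12, 11 and 9, and were named after their values were seen. Por encodes an oxidoreductase and is neither a clock component nor a PAR-bZIP gene. It had a peak in each of the counts above, and the list was not tested without it. Nfil3 belongs to this list. Without it, 14 of 25 members had a peak (exact adjusted p = 0.0213) and 8 of 25 had one with a score of 8 or more (adjusted p = 1.19e-04). With the limit set at 10 kb, 10 of 26 members had a peak (exact adjusted p = 0.0837).

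Cell cycle and survival genes formed the other list that stood out at high score. Of its 26 members, 14 had a peak within 50 kb (53.8%, odds ratio 2.91, two-sided Fisher's exact adjusted p = 0.0214), and 8 had one with a score of 8 or more (30.8%, odds ratio 8.75, adjusted p = 1.19e-04). Cdk4, which encodes a G1 cyclin-dependent kinase, had a promoter peak with a score of 10 located 192 bp upstream of its TSS. Cdk6, its close relative, had a peak with a score of 10 in intron 4 holding TTACATAA, 40.4 kb from the nearest TSS. E2f2, an E2F transcription factor gene, had a peak with a score of 9 with TTATGTAA, 12.02 kb upstream. The list did not pass for peaks within 1 kb of a TSS (3 of 26, odds ratio 1.38, exact adjusted p = 0.67). It also did not pass for peaks with a motif match (3 of 26, odds ratio 2.51, exact adjusted p = 0.248) or within 10 kb (odds ratio 3.04, adjusted p = 0.0546).

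**Figure D3:**
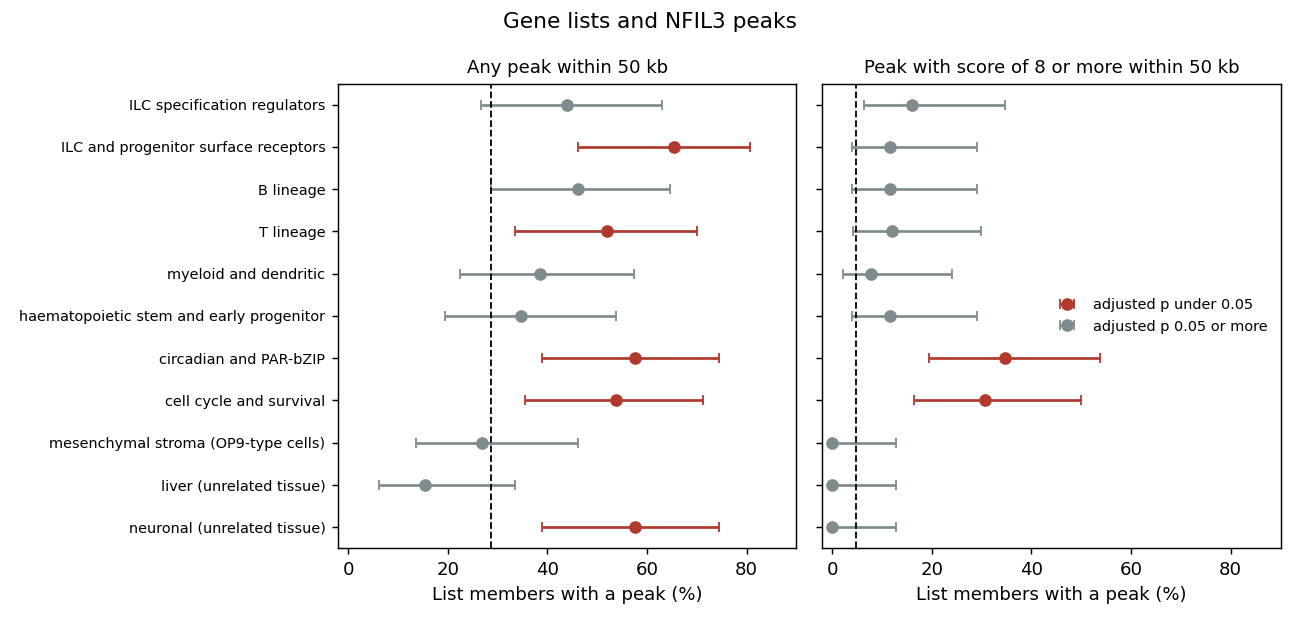
Percentage of members of each of the 11 gene lists with any peak within 50 kb (left) or with a peak scoring 8 or more within 50 kb (right), as points with 95% Wilson intervals, red where the Fisher's exact adjusted p is under 0.05. Dashed lines mark the share of the other protein-coding genes, and the circadian list lies at 57.7% and 34.6% while the neuronal list lies at 57.7% and 0.0%.

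Surface receptors of ILCs and their progenitors had the largest share of genes with a peak, while the list of ILC specification regulators did not pass the test. Of the 26 genes of the receptor list, 17 had a peak within 50 kb (65.4%, 95% interval 46.2 to 80.6, odds ratio 4.72, two-sided Fisher's exact adjusted p = 0.00119). With a motif match, 6 had one (odds ratio 5.79, exact adjusted p = 0.00778). Only 3 had a peak with a score of 8 or more (exact adjusted p = 0.205) and 3 one within 1 kb of a TSS (adjusted p = 0.67). Within 10 kb the exact adjusted p was 0.594. The list also holds Arg1, an enzyme gene, and Thy1, a surface glycoprotein gene, both without an assigned peak. The list of neuronal genes, from an unrelated tissue, gave 15 of 26 within 50 kb (57.7%). The receptor list was not tested against it. Il7r, the interleukin-7 receptor gene on which lymphoid progenitors depend, was the nearest gene of 4 peaks, of which 3 were intergenic and within 50 kb. The other lay 96.06 kb upstream of the TSS, in intron 23 of 32 of a transcript there. The peak with a score of 10 lay 44.5 kb upstream (chromosome 15, 9574668 to 9574837), and a neighbouring peak with a score of 7 held TTACATAA at 9577159 to 9577166. Cxcr5, a chemokine receptor gene, had a peak with a score of 9, 5.95 kb upstream, holding TTACGTAA. S1pr1, which encodes a receptor guiding lymphocyte egress, had peaks with scores of 8 and 4. Cxcr6 had no assigned peak, which does not exclude a peak assigned to a neighbour or removed by a filter.

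Of the 25 measured ILC regulators, 11 had a peak within 50 kb (44.0%, 95% interval 26.7 to 62.9, odds ratio 1.96, two-sided Fisher's exact adjusted p = 0.186) and 4 had one with a score of 8 or more (adjusted p = 0.114). Without Nfil3 the count was 10 of 24 within 50 kb and 3 of 24 at a score of 8 or more (exact adjusted p = 0.205). With no distance limit the odds ratio was 2.78 (exact adjusted p = 0.0338), and for peaks with a score of 5 or more it was 3.30 (adjusted p = 0.0112). Both of these include Nfil3 and were not repeated without it. Within 10 kb (5 of 25, exact adjusted p = 1), within 1 kb (2 of 25, adjusted p = 1) and with a motif match (3 of 25, adjusted p = 0.248) the list did not pass. Zbtb16, which encodes PLZF and marks ILC precursors, had 3 intron peaks with scores of 7, 6 and 6, and those with 7 and 6 in intron 2 held motif matches. Tox, a regulator of early ILC development, had intron 1 peaks with scores of 8 and 6 at 65.6 and 88.2 kb from the TSS and an intergenic peak with a score of 5, all outside the 50-kb limit and without a match. Runx3 had an intergenic peak with a score of 12 and a match 27.5 kb from its TSS, and the peak with a score of 9 assigned to Notch1 lay 13.1 kb from the TSS. Ets1 had a promoter peak with a score of 6, 121 bp upstream. Rora peaks scored 5 and 4 and lay over 100 kb away, at 114.11 and 129.74 kb. No peak was assigned to Id2, Tcf7, Gata3, Eomes or Tbx21. As for Cxcr6, this does not show that NFIL3 is absent there.

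B lineage genes gave 12 of 26 members with a peak within 50 kb (46.2%, odds ratio 2.14, two-sided Fisher's exact adjusted p = 0.145), and 5 of 26 with a motif-bearing peak (odds ratio 4.59, adjusted p = 0.0297). For peaks with a score of 5 or more the odds ratio was 3.63 (exact adjusted p = 0.00542). The list did not pass at scores of 8 or more (3 of 26, exact adjusted p = 0.205), within 1 kb (3 of 26, adjusted p = 0.67) or within 10 kb (8 of 26, adjusted p = 0.312). Ebf1, the factor that specifies B cells, had 4 peaks, the highest with a score of 15 and no match, 30.8 kb from the nearest TSS (chromosome 11, 44772107 to 44772276). Pax5, which commits cells to the B lineage, had 4 intron peaks with scores of 4 to 6 and no match. Bcl6, a germinal centre repressor gene, and Btla, an inhibitory receptor gene, each had a promoter peak with a score of 12 and a match, TGACATAA at Bcl6 and TTATGCAA at Btla. T lineage genes gave 13 of 25 with a peak (52.0%, odds ratio 2.70, exact adjusted p = 0.0308). Examples were Tcf12, an E protein gene, with a highest score of 11, and Bcl11a and Satb1, each with 8. Bcl11a and Lat2, which are not specific to T cells, counted among the members with a peak. The test was not repeated without them. The 2 peaks of Bcl11b, a panel gene, scored 3 and lay 53.85 and 105.26 kb away. For T lineage genes the exact adjusted p was 0.205 at scores of 8 or more (3 of 25), 0.611 within 1 kb (4 of 25) and 0.0903 with a motif match (4 of 25). It was 0.0486 within 10 kb (11 of 25, odds ratio 3.26), 0.0472 at scores of 5 or more (9 of 25) and 0.0338 with no distance limit (14 of 25), each by the same exact test.

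Myeloid and dendritic genes (10 of 26, odds ratio 1.56, adjusted p = 0.343) did not pass the two-sided Fisher's exact test within 50 kb. Neither did stem and early progenitor genes (9 of 26, odds ratio 1.32, exact adjusted p = 0.569). For peaks with a score of 5 or more, the stem and early progenitor list gave an odds ratio of 2.62 (exact adjusted p = 0.0472). It did not pass at scores of 8 or more (exact adjusted p = 0.205), within 1 kb (0.611), within 10 kb (1) or with a motif match (1). In the myeloid list the highest-scoring peaks were at Cx3cr1 (9), Tcf4 (8) and Csf2ra (7), and those in the stem and early progenitor list included peaks at Lmo2 (13) and Mef2c (10). None of these 5 peaks held a motif match.

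The 3 lists of other tissues differed widely, from 15.4% to 57.7% of genes with a peak within 50 kb, and the neuronal list passed the test. Mesenchymal genes, which OP9 stromal cells would express, had a peak in 7 of 26 cases (26.9%, exact adjusted p = 1), with highest scores of 7 at Fn1 and 4 at Col1a2 and Pdgfrb. Liver genes had a peak in 4 of 26 cases (15.4%, exact adjusted p = 0.263), with highest scores of 5 at Foxa1, Hnf4a and Ttr. Neuronal genes had a peak in 15 of 26 cases (57.7%, odds ratio 3.40, two-sided Fisher's exact adjusted p = 0.00723), as many as the circadian list. Their scores were low, the highest being 6 at Syp and 5 at Gad1 and Grin2b. None of the 26 neuronal genes had a peak with a score of 8 or more, which allows a share of up to 11.5% (3 counts of 26), and none had a peak within 1 kb of a TSS. Within 10 kb their odds ratio was 0.986. Circadian and neuronal genes differed in the count with a score of 8 or more (9 against 0 of 26, two-sided Fisher's exact p = 0.0017, adjusted over 12 comparisons of pairs of lists 0.0102) and within 1 kb (9 against 0 of 26, with the same p). They did not differ within 50 kb (15 against 15 of 26, exact adjusted p = 1), and the difference with a motif match did not pass (9 against 2 of 26, exact adjusted p = 0.115).

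Among protein-coding genes, Cntnap2 had the most peaks, 20, followed by Adgrl3 and Pde4d with 17 each and Lrp1b and Tpm3-rs7 with 15 each. Of these 84 peaks, 59 lay more than 50 kb from a TSS and 3 scored 8 or more. The median score was 4 at Cntnap2 and 3 at Adgrl3. Pde4d, a cyclic AMP phosphodiesterase gene, held a peak with a score of 13 in intron 1, 1.30 kb from an annotated TSS, with 2 motif sites.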

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

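No paired analysis was possible because the table carries no value per library. For the same reason no planned scaling, tool, pseudocount, filter, replicate or block alternative of the tagged-against-untagged comparison was run, and without mm39 sequence or annotation neither were the control windows, the 250-bp window, the random placement of peaks and the lists matched on territory. Alternatives at a score of 8 or more, within 1 kb, with a motif match, without Nfil3, on the mean, with the D-box core alone, and all those of the motif odds ratio were chosen after seeing the data. The score differences at promoters and at motif peaks, and the motif odds ratio, kept their direction and side of the threshold in every alternative run. Annotation shares moved with the score boundary. At scores of 5 or more and 8 or more, promoters made up 20.3% and 33.3%, exons 3.24% and 3.89%, and intergenic peaks 33.3% and 24.0%. Termination sites reached 3.33% at 5 or more and introns fell to 35.6% at 8 or more. Defined by distance, promoters made up 13.8%. The motif share was 8.0% within 50 bp of the centre and 16.5% at scores of 5 or more. The list odds ratios depended on the peaks counted. Within 10 kb, the calls ended for surface receptors (1.53, exact adjusted p = 0.594), circadian genes (2.59, adjusted p = 0.0837) and cell cycle genes (3.04, adjusted p = 0.0546), and neuronal and stem cell genes crossed to 0.986 each. With no distance limit, ILC regulators passed (2.78) and mesenchymal genes crossed to 1.37. At scores of 5 or more, ILC regulators (3.30), B lineage (3.63) and stem cell genes (2.62) passed and neuronal genes did not (1.48). At 8 or more, receptors (2.56) and T lineage (2.67) no longer passed and neuronal genes had 0.0. Within 1 kb, receptors and cell cycle genes (1.38 each) and T lineage (2.02) no longer passed, and ILC regulators (0.921), myeloid (0.883) and neuronal genes (0.0) crossed below 1. With a motif match, B lineage passed (4.59), T lineage (3.67), cell cycle (2.51) and neuronal genes (1.60) did not, and stem cell genes crossed to 0.769. The cause was not tested. Fewer genes have a peak under each stricter choice, which leaves the lists of 25 or 26 genes with less power. The odds ratios themselves also moved, and in both directions. That of receptors fell from 4.72 to 1.53 within 10 kb, and that of B lineage rose from 2.14 to 3.63 at scores of 5 or more. No list changed its call without Nfil3 within 50 kb or at a score of 8 or more, the only counts from which Nfil3 was removed. The circadian list passed in every alternative except 10 kb.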

Other observations

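Promoter peaks that held a motif match and had the highest scores belonged to genes outside the fixed lists. They were chosen after their values were seen. After Adnp, Wbp2 and Coq10b, they were at Baz1b, a chromatin remodeller gene (score 21, core TTACATAA), Abhd11 (19, TTACGTAA), Irf2bp1 (19, TTATGTAA), Pbld2 (18, TTATGCAA), Scml4 (17, TGACATAA), the lysosomal protease gene Ctsl (16), the DNA repair gene Paxx (16, TTAAGTAA), and, with scores of 15, the translation elongation factor gene Eef2, the lipid transfer gene Mttp, the vitamin K carboxylase gene Ggcx, the integrin gene Itgax and Aktip.

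The peak numbers in the table count from 1 within each chromosome and follow the score (Spearman's rho from -0.986 to -0.962 over 20 chromosomes, across peaks, which are not independent replicates). They also show gaps. Of the first 10 numbers per chromosome 71.0% were present (142 of 200, 95% interval 64.4 to 76.8), of numbers 11 to 100 87.3%, of those above 100 and up to 1000 34.5%, and of those above 1000 and up to 10000 4.16%. The largest number on chromosome 1 was 67160, for 1284 peaks listed there, and the lowest number present on chromosome 9 was 18.

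All tests below were chosen after the results that prompted them were seen. The 2 highest-scoring peaks of the list lie in exon 2 of Nfil3, the gene that was delivered by retrovirus. A candidate explanation is DNA of the integrated vector, whose coding sequence would align to that exon. It cannot account for the intron 1 peak, with a score of 15, which spliced coding sequence would lack, and 0 peaks were assigned to Thy1, the marker of the same vector, which decides nothing because filtering may have removed one. Of the 2 exon peaks 0 held a motif match, which argues against binding to a motif within them. Vector DNA at the exon and binding without a motif match both stay open, since the table holds no value for the untagged libraries, whose cells also carried an NFIL3 vector.

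The share of motif-bearing peaks was larger at higher scores. GC content argues the other way, since the odds ratio was 3.16 unadjusted, 4.32 within GC classes and 3.97 (95% interval 3.47 to 4.54) within joint classes of GC, CpG density and annotation. A hypothesis is that many low-scoring peaks hold a match only by chance. The share of sites in the central 50% of the positions compared around the peak centre was counted. It was 55.2% at scores of 5 or more (708 of 1282) and 48.7% at 2 to 4 (446 of 915). An even spread gives 50%, and the 2 shares differed (two-sided Fisher's exact p = 0.0028). Shares by score class had been seen when this prediction was written, so the p is no separate support for the hypothesis. At scores of 8 or more the share was 54.5% (261 of 479, p = 0.0549 in a binomial test against an even spread). It was 51.4% at 10 or more (126 of 245, 95% interval 45.2 to 57.6). The interval at 10 or more holds both the even spread and the 55.2% seen at 5 or more. It therefore cannot tell whether sites in the strongest peaks are centred. Matches were more frequent among these peaks, but 36 of the 68 peaks with scores of 16 or more held no match. Centring cannot decide the hypothesis, since the shares had been seen and those of the strongest peaks are imprecise. The hypothesis stays open.

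Neuronal genes, a list of an unrelated tissue, had a peak within 50 kb as often as circadian genes. A candidate explanation, prompted by the low scores at these genes, is that their peaks are distal ones. With no distance limit, 17 neuronal and 16 circadian genes had a peak, the nearest up to 206 and 114 kb from the TSS. The median distance of the nearest peak was 17.1 kb for the neuronal and 0.784 kb for the circadian genes. This difference did not pass a two-sided permutation test (p = 0.116). The test covers these larger sets and not the 15 genes of each list with a peak within 50 kb. Within 10 kb, 5 of 26 neuronal genes (odds ratio against other genes 0.986) and 10 of 26 circadian genes (2.59) had a peak. The neuronal excess over other genes was thus absent within 10 kb. Within 1 kb of a TSS, 0 of 26 neuronal and 9 of 26 circadian genes had a peak (two-sided Fisher's exact p = 0.0017, adjusted 0.0102), a count already seen that goes with the explanation, which stays open. The genome territory of each gene was not measured.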
